A study of Mus musculus with 4 samples.

How the data were processed

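Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with an antibody to Tet1, a dioxygenase that oxidises 5-methylcytosine. The cells were spermatogonia, the mitotic germ cells of the testis, taken by flow sorting (20000 cells per the labels) from wild-type (WT) mice and Tet1 knockout (KO) mice of strain 129 at 3 months of age. There were 4 libraries, 1 Tet1 ChIP and 1 input (chromatin sequenced without antibody) per genotype. The files analysed here were the 2 peak lists, 1 per genotype. Per the submitters' processing notes, Trim Galore, Bowtie2, SAMtools, deepTools and MACS2 were used and the build was mm10, with roles and settings not given in the sources used here.

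Per the file headers, peaks were called by MACS 2.1.1.20160309 on each ChIP library against the input of the same genotype, so nothing was pooled. The headers give a q cutoff of 0.5, which is lenient, and the human preset for effective genome size, although the organism is mouse. Single-end tags were used, 1 tag was kept per position and strand, fragments were extended to 299 bp (WT) and 300 bp (KO), and the larger library was scaled to the smaller. After this filter the WT ChIP held 3081692 of 4241117 tags and its input 3546238 of 4477283. The KO ChIP held 2235818 of 2962767 tags and its input 3739856 of 4578898. Redundant tags made up 27% of the WT ChIP, 21% of the WT input, 25% of the KO ChIP and 18% of the KO input. In both genotypes the input was the larger library, and was scaled by 0.869 (WT) and 0.598 (KO).

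The deposited pileup is a signal, the number of extended ChIP tags over the summit, not scaled because the ChIP was the smaller library. The deposited fold enrichment is the ratio of the pileup plus 1 to the local background from the scaled input plus 1. The deposited −log10 p and −log10 q values come from a Poisson test of the pileup against that background and its Benjamini-Hochberg adjustment. All peak scores are the authors' own. The local background at each summit was recovered here from the deposited pileup and fold. Recomputing the Poisson p from these gave the deposited value within 5% for 373 of 373 WT peaks and 247 of 247 KO peaks. The lowest background in each list, 0.341 tags in WT and 0.248 in KO, equalled the genome-wide value that the headers imply.

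Gene positions were taken from a RefSeq gene table of assembly GRCm38.p6, which has the mm10 coordinates. It gives gene spans and types without strand, exons or sequence. Promoters, exons, introns, untranslated regions and base composition were therefore not analysed here. In place of promoters, a summit was called near a gene end when it lay within 3000 bp of either end of an annotated gene, and otherwise inside a gene or intergenic. The sequence composition planned at the outset was not run for lack of a genome.

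The comparisons, the overlap rule (1 bp), the gene lists, the rule for named peaks and most alternatives were fixed before the data were examined. The named peaks were the 10 WT-only and 10 KO-only peaks with the highest fold enrichment, the 5 shared WT peaks with the highest fold, the 10 WT-only and 5 KO-only peaks near a gene end with the highest fold, up to 3 members of each gene list with a peak, and Tet1 itself. A gene was assigned to a peak when the summit lay in it or within 3000 bp of it. Some peaks that this rule selects are counted in the totals but not reported here by name. Other items were named after their values were seen. The classes of peaks were also set after the lists had been read. Peaks on mitochondrial DNA or unplaced contigs formed the first class. Chromosomal peaks with a local input background of at least 10 times the genome-wide value formed the second (high input). Of the others, called low-input, those with a summit within 500 bp of a gene for tRNA, small nuclear RNA, small cytoplasmic RNA, rRNA, Y RNA or the RNA of RNase P or MRP formed the third (small RNA gene), and the rest the fourth (other low-input). The clusters of peaks named by position, the depth matching and the effective genome size alternative were likewise chosen after seeing the data.

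Shares have exact binomial (Clopper-Pearson) 95% intervals, pileups have exact Poisson 95% intervals, and ratios of 2 pileups have exact conditional 95% intervals, scaled by the ChIP tags left after filtering. With 1 library per group there was no replicate check, and no test given here compares the genotypes as conditions. The 1 test between the lists, a Fisher's exact test of WT-only against KO-only peaks near gene ends in the closing part, compares these 2 libraries. The intervals cover counting error only, and peaks in clusters are not independent. Random placements (1000) moved each peak to a random position between the first and last annotated gene of its chromosome, keeping its width. Gene lists were set against 10000 random lists matched on gene length. Within each list, median scores of shared and unshared peaks were compared by a two-sided permutation test (100000 resamples), 16 tests in the family, Benjamini-Hochberg adjusted. The tests with peaks within 1000 bp counted as shared used 10000 resamples and were not adjusted. Such a test compares peaks of a library, not conditions. The overlap, location and permutation steps were tested on simulated data. All 60 of 60 planted overlaps were found, with 0 false among 292 other peaks, and 50 of 50 planted small RNA summits were found. The permutation test gave p below 0.05 in 7 of 100 simulations without a difference and in 20 of 20 with a 1.5 times higher fold, and the ratio interval held the true value in 97.2% of simulations. Depth was matched by thinning WT pileups binomially to the KO tag number 1000 times. A thinned peak counted as kept when its summit p-value was at least as low as that of the weakest KO peak. Peak width was not checked again, so the numbers kept may be too high. Thinning can remove peaks but cannot create them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.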

Results

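Tet1 ChIP-seq was done in sorted spermatogonia of WT and Tet1 KO mice at 3 months of age, with 1 ChIP and 1 input library per genotype. The KO library measures what the antibody and the procedure recover in cells from the knockout mice. The comparison thus asks which peaks are found in WT and which in KO cells, in which loss of Tet1 protein was not checked. The libraries were shallow, with 3081692 WT and 2235818 KO ChIP tags after duplicate removal, a ratio of 1.38. Coordinates are those of mm10.

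The WT list held 373 peaks and the KO list 247, a difference of 126. They covered 175088 bp in WT and 135486 bp in KO. Most peaks were low. The median summit pileup was 8 tags in WT (range 4 to 559) and 12 in KO (range 4 to 557), and the median fold enrichment over input was 5.22 in WT and 4.81 in KO. At a q of at most 0.05, 333 WT and 237 KO peaks were left. When WT pileups were thinned to the KO depth, a mean of 311 WT peaks (range 293 to 333) kept a p-value at least as low as the weakest KO peak. With a fold of at least 5 there were 198 WT and 116 KO peaks. With a −log10 q of at least 5 there were 142 and 144, of which 16 WT and 44 KO peaks lay on mitochondrial DNA or contigs and 22 and 31 on chromosome 9. Low-input peaks not overlapped by a peak of the other list that also passed this limit numbered 62 and 21. Some of these were overlapped by a weaker listed peak.

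The Tet1 gene itself (chromosome 10, 62804570 to 62887469) had no peak in either list, inside it or within 3000 bp. The nearest WT peak lay 9.47 Mb away and the nearest KO peak 17.2 Mb away. A peak list gives no information on the deleted part of the gene or on the Tet1 protein left in the KO cells, so these values do not check the genotype labels.

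The lists overlapped far more than random positions. Of the 373 WT peaks, 122 (32.7%, 95% interval 28.0 to 37.7) were overlapped by a KO peak, and 122 of the 247 KO peaks (49.4%, 43.0 to 55.8) by a WT peak. On the chromosomes, 103 of 352 WT peaks were overlapped, against a mean of 0.029 and a maximum of 1 in random placements. The share differed between the classes. It was 85.2% (72.9 to 93.4) for the 54 WT peaks in regions of high input, 51.5% (39.0 to 63.8) for the 68 at small RNA genes and 9.57% (6.09 to 14.1) for the 230 other low-input peaks. In the KO list the same shares were 66.7% of 66, 65.4% of 52 and 30% of 80. On mitochondrial DNA or contigs the share was 90.5% of 21 WT peaks and 40.8% of 49 KO peaks. Median WT pileups were 99.5 tags (high input), 9 (small RNA gene) and 6 (other low-input). Kind of sequence is therefore not separated from signal strength. The WT list exceeded the KO list mostly in the other low-input class, with 230 peaks against 80.

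**Figure D1:**
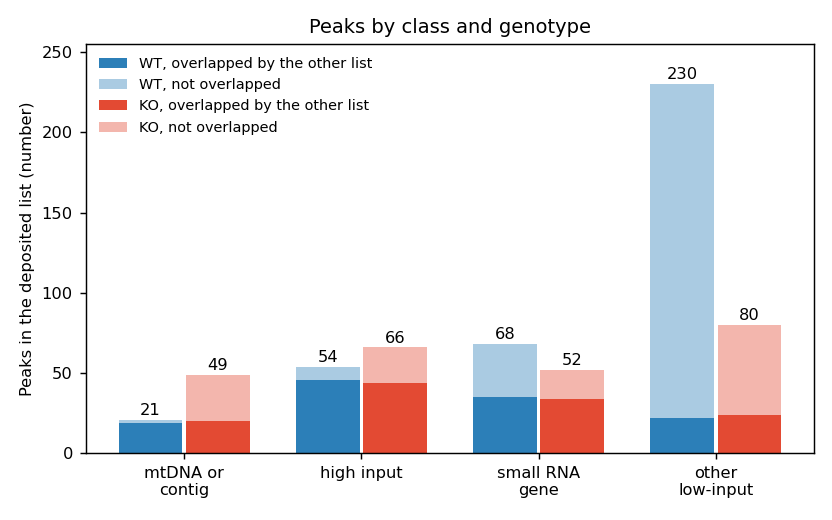
Number of peaks in the deposited WT and KO lists in 4 classes, split into peaks overlapped by the other list (dark) and not overlapped (light). The other low-input class held 230 WT and 80 KO peaks, of which 22 and 24 were overlapped.

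The highest pileups lay where the input was also high. The maximum of both lists was on chromosome 2 at 98666690 to 98667196, with 559 tags in WT and 557 in KO. At the start of chromosome 9, a block from 3000244 to 3035280 held 17 WT peaks with a median pileup of 321 tags and a median fold of only 1.64, and all 17 were overlapped by KO peaks. The KO list had 27 peaks between 3000174 and 3038241, with a median pileup of 288 and a median fold of 2.36. The unplaced contig JH584304 held 16 WT peaks (median pileup 239.5, median fold 1.68), all overlapped, and 38 KO peaks (median pileup 161.5, median fold 2.37). Mitochondrial DNA was covered almost end to end in both lists, by 1 WT peak of 16266 bp (pileup 197, fold 9.54) and by 2 KO peaks (pileups 125 and 146). A pair of mitochondrial-type pseudogenes on chromosome 1, Gm10925 and Gm10222 (24611538 to 24616175), had a pileup of 120 in WT and 82 in KO, and was among the 5 shared peaks of highest fold (13.8 in WT).

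**Figure D2:**
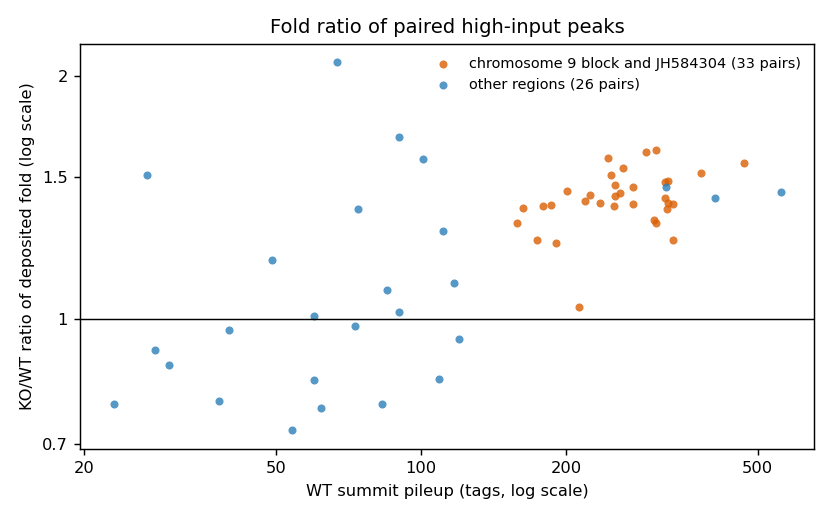
KO/WT ratio of the deposited fold (vertical axis, log scale) against WT summit pileup (horizontal axis, tags, log scale) for 59 high-input peaks paired 1 to 1 between the lists, 1 point per pair, with a line at a ratio of 1. The 33 pairs of the chromosome 9 block and the JH584304 contig have ratios of 1.03 to 1.62, and the 26 pairs of other regions 0.727 to 2.08.

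**Figure D3:**
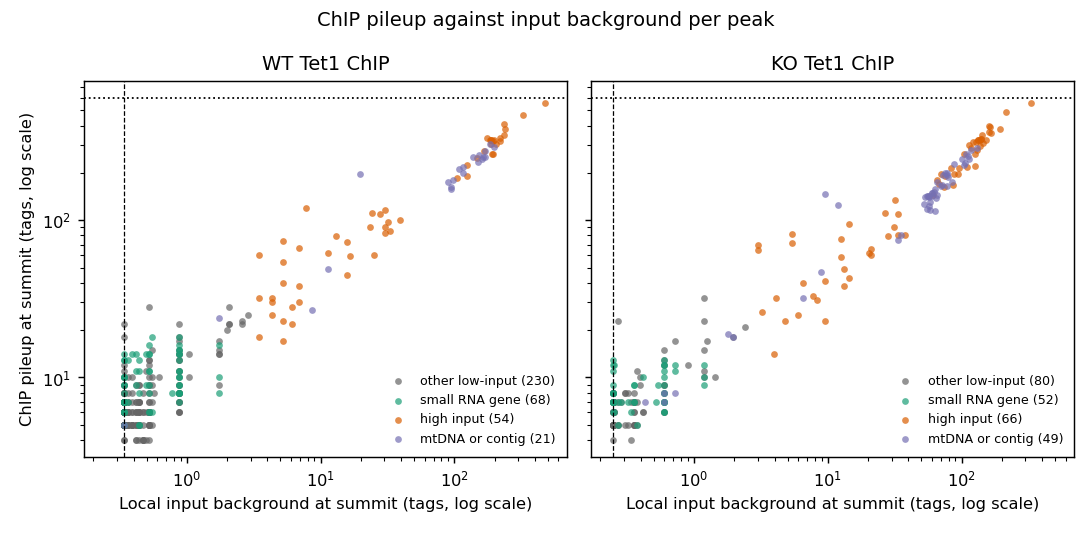
Summit pileup (vertical axis, tags, log scale) against local input background (horizontal axis, tags, log scale) for each listed peak, WT on the left and KO on the right, coloured by class. The dashed line marks the genome-wide background (0.341 in WT, 0.248 in KO) and the dotted line the largest pileup possible with 1 tag per position and strand (598 and 600).

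Small RNA genes, among them the tRNA genes that RNA polymerase III transcribes, were enriched among the peaks of both genotypes. In WT, 69 of 352 chromosomal peaks lay within 500 bp of such a gene, against a mean of 0.202 and a maximum of 3 in random placements. In KO it was 52 of 198, against a mean of 0.128 and a maximum of 3. Transfer RNA genes accounted for 49 WT peaks, next to 75 of the 408 annotated tRNA genes, and 40 KO peaks, next to 58. Of these genes, 40 were the same in both lists, while independent lists of that size would share 10.7. Small nuclear RNA genes had 16 WT and 10 KO peaks, 8 of each list overlapped by the other. None of the 63 annotated rRNA genes had a low-input peak in either list.

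At named members of this group found in both lists, the intervals of the depth-corrected WT/KO ratio held 1. At Rn7sk, the RNA of the 7SK particle that restrains transcription elongation (chromosome 9, 78175494 to 78175880), the pileup was 18 tags in WT and 11 in KO, a depth-corrected WT/KO ratio of 1.19 (0.531 to 2.78). At Rnu1a1, a U1 spliceosomal RNA gene inside Tex14 (chromosome 11, 87422629 to 87423213), it was 16 in WT and 10 in KO, a ratio of 1.16 (0.495 to 2.86). At Rn7s1, which encodes the RNA of the signal recognition particle, the pileups were 11 and 7 (ratio 1.14, 0.404 to 3.47). Summed over the 33 small RNA peaks paired 1 to 1 between the lists, there were 364 WT and 286 KO tags, a ratio of 0.923 (0.789 to 1.08). Both libraries had to pass the caller for a peak to enter this sum, so peaks lost in KO are not in it.

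Other members were listed in 1 genotype. Among the 10 WT-only peaks of highest fold were the small nuclear RNA gene Gm22317 (chromosome 12, 54738415 to 54738823, 18 tags, interval 10.7 to 28.4, fold 12.3), Gm24407 next to Sirt4 (chromosome 5, 115489964 to 115490334, 13 tags, fold 10.4), Rnu5g, a U5 spliceosomal RNA gene (chromosome 9, 65201631 to 65202066, 14 tags, fold 9.87), and the tRNA genes n-TLaag7, n-TMcat15 and n-TLaag5 (chromosome 13, 21169613 to 21170355, 13 tags, fold 10.3). The WT list also had 4 peaks at the U3 genes Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 inside Tex14, of 7 to 15 tags, with none in KO. The highest was Rnu3b2 (chromosome 11, 87471166 to 87471505, 15 tags, fold 8.56). KO-only peaks included the Y RNA gene Rny1 (chromosome 6, 47788097 to 47788397, 9 tags, fold 7.36), n-TVcac7 beside Trim41 (chromosome 11, 48818328 to 48818825, 13 tags, fold 8.76), n-TRtct1 and n-TVtac1 (chromosome 19, 12011565 to 12011882, 9 tags), and 3 further ones of 8 tags each at Gm26444, n-TTagt6 and n-TMcat9, the last beside the histone gene H4c8.

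A region of chromosome 6 that begins at Rn4.5s, a 4.5S RNA gene, had evenly spaced peaks and differed between the lists. From 47654862 to 47685611 there were 8 WT peaks of 20 to 32 tags, a median of 4366 bp apart, and no KO peak overlapped any of them. Their spacing ran from 4256 to 4401 bp. The 8 peaks form a cluster and are not to be read as independent sites. Whether they are copies of a repeat was not tested, because no genome sequence was used here. The KO list had a single peak of 18 tags at 47650704, beside this stretch. From 47739645 to 47763621 both lists had 6 peaks, all overlapping, with median pileups of 57 in WT and 48.5 in KO. The peak at Gm40367 (47663505 to 47663953, 28 tags, interval 18.6 to 40.5, fold 9.42) was among the 10 WT-only peaks of highest fold, and that at Gm52861 (47743853 to 47744485, 60 tags in WT, 72 in KO) among the 5 shared peaks of highest fold. Input background in WT was at least 5.09 times the genome-wide value at each of these peaks.

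**Figure D4:**
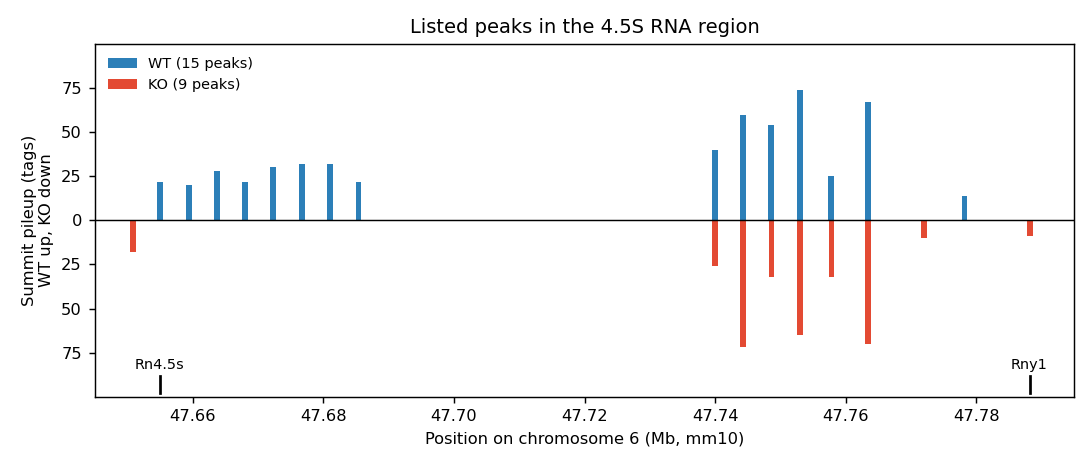
Summit pileup (tags) of listed peaks along 150 kb of chromosome 6, WT upward (15 peaks) and KO downward (9 peaks), with Rn4.5s and Rny1 marked. The 6 peaks on the right appear in both lists, and the 8 WT peaks on the left have no KO counterpart.

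The 3 low-input WT peaks of highest fold were shared by both genotypes. The highest fold of each list was inside Abcc9, which encodes a regulatory subunit of ATP-sensitive potassium channels (chromosome 6, 142662137 to 142662910). Its pileup was 28 tags in WT (fold 19.08) and 23 in KO (fold 18.9), a depth-corrected ratio of 0.883 (0.491 to 1.61). At Dolpp1, a dolichyl diphosphate phosphatase gene (chromosome 2, 30391898 to 30392453, near a gene end), the pileup was 22 in WT and 8 in KO, a ratio of 1.995 (0.855 to 5.18). Inside Gpc6, a glypican gene (chromosome 14, 117932370 to 117932775), it was 18 and 15, a ratio of 0.871 (0.414 to 1.86). The polyubiquitin gene Ubb had 10 and 11 tags, a ratio of 0.660 (0.251 to 1.71). Over all 54 low-input peaks paired 1 to 1 between the lists, none had an interval that excluded 1. The summed ratio was 0.933 (0.830 to 1.05). The single intervals are wide at these pileups, and only peaks called in both libraries enter. These values therefore do not show equal signal in the 2 genotypes.

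WT-only peaks outside small RNA genes were low and often near gene ends. The highest fold was at the long noncoding RNA gene Gm52405 and Pgm5, a phosphoglucomutase-like gene (chromosome 19, 24857447 to 24858440, 22 tags, interval 13.8 to 33.3, fold 12.3). Others were at Ccdc12 and Nbeal2 (chromosome 9, 110656516 to 110656895, 18 tags, fold 10.2), A430018G15Rik and Arl5a (chromosome 2, 52425109 to 52425435, 12 tags, fold 9.69), and an intergenic position on chromosome 12 (97061359 to 97061728, 13 tags, fold 9.21). KO-only peaks of the same kind were at Gm39011 and Ldha, the lactate dehydrogenase A gene (chromosome 7, 46852682 to 46853045, 23 tags, interval 14.6 to 34.5, fold 10.9), inside Ppp1r9a (chromosome 6, 4923836 to 4924197, 13 tags, fold 8.76), near an end of Gpr89 (chromosome 3, 96905287 to 96905616, 8 tags) and on chromosome Y (4074481 to 4075030, 8 tags).

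Within a list, shared and unshared peaks differed in strength. Among low-input WT peaks the median fold was 6.94 for the 57 shared and 5.22 for the 241 unshared peaks (permutation p = 1e-05, the smallest that 100000 resamples can give). Among low-input KO peaks it was 6.41 for 58 shared and 5.62 for 74 unshared peaks (permutation p = 0.0128, adjusted p = 0.0158). Over all WT peaks the direction was opposite, 4.61 for shared and 5.22 for unshared peaks (permutation p = 0.00712, adjusted p = 0.0104). The shared WT peaks of high-input regions had a median fold of 2.43. By −log10 q the shared WT peaks were the stronger, with medians of 8.51 against 2.55 (permutation p = 1e-05), and with peaks within 1000 bp counted as shared the fold difference was -0.404 (permutation p = 0.0548). Over all KO peaks the median folds were equal at 4.81 with an overlap of 1 bp (permutation p = 1). They differed by -0.725 with peaks within 1000 bp counted as shared (permutation p = 0.0258), and the median −log10 q was 9.99 for shared and 4.93 for unshared KO peaks (permutation p = 0.00012).

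Peaks were concentrated near gene ends in both genotypes. In WT, 183 of 352 chromosomal peaks (52.0%, 46.6 to 57.3) lay within 3000 bp of a gene end, against a mean of 15.6% and a maximum of 22.7% in random placements. In KO it was 98 of 198 (49.5%, 42.3 to 56.7), against a mean of 16.1%. These counts include the small RNA class, 68 peaks in WT and 52 in KO. Its peaks lie within 500 bp of a short gene and so near a gene end by construction. With protein-coding genes alone the shares were 32.95% in WT and 25.3% in KO, and no random placements were made for these. Gene interiors held 26.4% of WT and 15.2% of KO peaks, against 36.6% and 37.5% in random placements. Intergenic sequence held 21.6% of WT and 35.4% of KO peaks, against 47.8% and 46.5%. The chromosome 9 block, with 17 WT and 27 KO peaks, adds to the KO share, since nearly all its KO peaks were intergenic. Unshared peaks of the other low-input class lay within 1000 bp of a protein-coding gene end in 52 of 208 cases in WT (25%, 19.3 to 31.5) and 13 of 56 in KO (23.2%, 12.98 to 36.4). Random placements gave means of 3.02% and 2.96%.

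Chromosome 11, rich in genes, had 41 WT peaks, 2.58 times what its length predicts, and 22 KO peaks, 2.46 times. Small RNA genes accounted for 17 and 15 of these. Chromosome Y had 25 WT and 12 KO peaks, most of them between 4016178 and 4147833, where 20 WT and 9 KO peaks of 4 to 11 tags lay and 1 of each list overlapped. On chromosome X, the stretch from 169988411 to 170022428, chosen for its WT peaks, with Erdr1 and Mid1, had 7 WT peaks of 5 to 17 tags and no KO peak. Nearer the end of the chromosome, the KO list had peaks at 170758143 (60 tags, fold 2.78) and 170880935 (23 tags, fold 4.15) and the WT list none. Both were high-input peaks, with a KO input background of 84.2 and 19.3 times the genome-wide value.

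Of the 281 genes in the 14 fixed lists, 9 had a WT peak and 4 a KO peak. Random lists matched on length had a mean of 3.07 genes with a WT peak, and 35 of 10000 had as many as 9. For KO the mean was 1.06, and 226 of 10000 had as many as 4. The excess was strongest in the housekeeping list, whose 3 WT genes were matched by 2 of 10000 random lists. It was 40 for the meiosis list, 199 for germline genome defence and 1279 for differentiating spermatogonia. In KO it was 16 for housekeeping and 60 for meiosis. Random lists were not matched on expression. In the meiosis list (27 genes), WT peaks were found at Stag3, a meiotic cohesin subunit gene (6 tags, interval 2.20 to 13.1, fold 4.69) and inside Tex14, where all 5 summits lay at Rnu1a1 or the U3 genes. KO peaks were found inside Tex14, at Rnu1a1 alone, and at Syce1, a synaptonemal complex gene (6 tags, fold 5.15). In the germline genome defence list (18 genes), WT peaks lay inside Dazl, an RNA-binding regulator of germ cells (5 and 6 tags, folds 4.32 and 5.13), and inside Piwil2, a gene of the piRNA pathway (6 tags, fold 4.77), with no KO peak. In the list of differentiating spermatogonia (12 genes), WT had a peak inside Sohlh1, a germline transcription factor gene (5 tags, interval 1.62 to 11.7, fold 4.47), and KO had none.

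The housekeeping list (18 genes) had WT peaks at Ubb and near an end of Polr2a, the gene of the largest RNA polymerase II subunit (7 tags, fold 5.96), and KO peaks at Ubb (11 and 7 tags) and Rpl4 (7 tags, fold 6.39). No peak in either list fell on a member of the lists of undifferentiated spermatogonia, DNA methylation machinery, imprinted genes, Polycomb-type developmental regulators, the cell cycle, Sertoli cells, Leydig cells, peritubular and interstitial cells, macrophages and endothelium, or spermatids. For each of these lists, random lists had a mean of at most 0.508 genes with a WT peak and 0.179 with a KO peak. These absences therefore give no information on Tet1 at these genes. Each germline peak outside Tex14 had 5 or 6 tags, and their q-values ran from 0.00326 to 0.0497. At this depth the presence of such a peak in 1 list and its absence from the other do not show a difference between the genotypes.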

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

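The alternatives with q of at most 0.05, the mouse effective genome size, WT pileups thinned to the KO depth, the small RNA window of 1000 bp and low-input limits of 5 and 20 times were chosen after seeing the data, and the others before. Of the values that answer a comparison, 69 stayed within their spread, on their side of the threshold or within 1.5 times, 29 moved further, 2 reversed, 2 passed the threshold and 1 lost it. With the mouse genome size all 44 folds of named peaks stayed above the lower 95% counting limit of the deposited fold. They could hardly fall below it, because only the genome-wide background rises (0.341 to 0.493 tags in WT, 0.248 to 0.359 in KO). Some of the 69 also could not change. Gene end, chromosome 9, small RNA, low-input and gene list values use chromosomal peaks only, so keeping the autosomes, X and Y left them the same. The 69 and 44 are therefore no measure of robustness. With peaks of −log10 q of at least 5, the WT and KO counts were 142 and 144, so the difference turned to -2. The overlap was 50.7%, gene end shares were 60.3% (WT) and 40% (KO), small RNA peaks 34 and 20, unshared low-input peaks 62 and 21, and list genes 3 and 2. With folds of at least 5, the counts were 198 and 116 (difference 82), the overlap 23.7%, gene end shares 64.8% and 69.4%, mitochondrial or contig peaks 2 and 8, chromosome 9 peaks 6 and 3, WT unshared low-input peaks 145 and WT list genes 5. Both filters leave fewer peaks. Sharing was judged among the peaks left, so a peak counted as unshared can overlap a listed peak that was filtered out. The fold filter removes all peaks of the chromosome 9 block. Thinning, judged by summit p-value alone, reduced the WT minus KO difference to 63.8. Equal numbers of peaks gave an overlap of 42.5%. Gene end shares were 42.3% (1000 bp) and 61.1% (5000 bp) in WT, and 32.95% (WT) and 25.3% (KO) with protein-coding genes alone. Counting peaks within 1000 bp as shared moved the shared minus unshared fold to -0.404 in WT (permutation p = 0.0548) and to -0.725 in KO (permutation p = 0.0258), and the cause was not tested. With −log10 q as the strength it was 5.96 in WT, opposite to the fold, and 5.06 in KO, and shared peaks have the higher pileups. With the mouse genome size, 288 of 333 WT and 233 of 237 KO peaks kept the p of q 0.05. The alternatives for sequence composition were not run, because no genome was used here, and those for distance to a transcription start were run on gene ends. No paired analysis was possible because each group had 1 library, and no library could be left out. Depth limits the low-input peaks, since a peak of 5 tags has a 95% interval of 1.62 to 11.7.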

Other observations

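All tests in this part were chosen after the result was seen. At the blocks of chromosome 9 and the JH584304 contig, the deposited fold was higher in KO than in WT in 33 of 33 paired peaks, by a median of 1.40 times (quartiles 1.37 to 1.48). Scaling of the larger input after duplicate removal may raise KO folds where tags are dense, because the input scale factors differ by 1.45 times and 1 tag was kept per position. Outside the blocks, the 3 pairs as dense had a median KO/WT ratio of 1.44, and the 23 less dense pairs 0.979 (KO higher in 11). With unscaled input, the 33 block pairs had a median ratio of 0.969 (quartiles 0.950 to 1.02, KO higher in 11). The less dense pairs then had 0.699. Leaving out the scaling lowers these ratios by construction, so they do not show the cause. More ChIP signal in the KO cells also stays open: the pileup scaled by tag number was 1.33 times as high in KO as in WT, but it was 1.28 times as high at the less dense pairs, where the median fold ratio was not above 1. The 2 cannot be told apart, because 3 pairs are too few and the reason why pileups did not follow depth was not tested.

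Small RNA genes had peaks in both lists. Binding of Tet1 protein as the only source is argued against by the 52 KO peaks at small RNA genes, against a maximum of 3 in random placements, if the KO cells lack the antibody's target, which was not checked. A partial contribution of Tet1 stays open, because the WT/KO ratio of 0.923 covers only peaks paired between the lists and leaves out the 33 of 68 WT peaks with no KO counterpart. Collapsed genome copies would raise the input as much as the ChIP, but the median input background at WT small RNA peaks was 1.45 times the genome-wide value (upper quartile 2.55), against a median fold of 6.33. The class leaves out high-input peaks by definition, but it held 68 of the 69 WT summits near small RNA genes. The lowest fold of any low-input WT peak was 3.29, so part of this contrast follows from peak calling. Signal that open or highly transcribed chromatin gives in any immunoprecipitation, or another target of the antibody, may account for these peaks and was not tested.

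The WT list had more low-input peaks, 298 against 132. After thinning to the KO depth, a mean of 239 WT low-input peaks (range 221 to 260) reached the summit p-value of the weakest KO peak. That was a high-input peak (Poisson −log10 p of 4.25), while the weakest low-input KO peak had 4.54. Peak width was not checked again, so the number kept may be too high. The thinning therefore does not decide whether lower depth of the KO library was the whole cause. Random positions called at a lenient threshold are argued against as the only source of the unshared WT peaks of the other low-input class. Of these peaks, 25% lay within 1000 bp of a protein-coding gene end, against a maximum of 7.69% in random placements. How many of the rest were random calls was not tested. Binding of Tet1 protein at gene ends could add low-input peaks in WT alone. WT-only and KO-only peaks of the other low-input class lay there in 25% and 23.2% of cases (Fisher's exact test, p = 0.862, odds ratio 1.10, 0.530 to 2.41), and that interval is too wide to decide. Differences in ChIP efficiency between the 2 preparations cannot be separated from genotype with 1 library each.

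Outside Tex14, the spermatogonial differentiation, meiosis and genome defence lists had 5 genes with a WT peak (among them Sohlh1, Stag3, Dazl and Piwil2) and 1 with a KO peak (Syce1). When WT pileups were thinned to the KO depth, a mean of 3.87 of the 5 WT genes kept a peak by summit p-value alone (range 0 to 5). Of the 1000 thinnings, 12 left 1 or none. The lists were joined after their counts were seen and the genes taken because they had a WT peak, so these values describe the effect of depth on the WT list and are no test of a difference between the genotypes.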
